A study of Mus musculus with 19 samples.

How the data were processed

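The bulk files held 24094 genes each, keyed by Entrez ID, for 17 libraries, and the single-cell files held 2 filtered matrices; all 19 deposited samples were used and no column was left out. The values of the bulk files were whole numbers and were taken as the deposited count of reads per gene, and those of the matrices as the deposited count of UMIs per gene and cell, as provided by the authors. A symbol and an mm10 position were found for 24039 IDs, and the other 55 held at most 0.0291% of the counts of a library. The submitters' processing notes name bcl2fastq 2.18.0, STAR and DESeq2 for the bulk libraries, Cell Ranger 3.0.2 for the single cells and the mm10 reference; versions of STAR and DESeq2 were not given. Libraries were made with SMART-Seq v4 and KAPA Hyper Prep, and the 2 single-cell libraries were pooled before sequencing, per the labels.

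Per the labels, preparation was described in 4 texts, A for TAM, MTM and Monocyte, B for DC1 replicate 1, C for DC1 replicate 2, DC2, Irf8FL_TAM and CD11cCre_Irf8FL_TAM, and D for the single cells. RNA integrity ran from 1 to 9.5 in text A, 6.8 to 10 in text B and 3.6 to 10 in text C. The 10 genes with the most counts took 20.3 to 22.2% of counts in TAM libraries, 10.9 to 12.1% in MTM and 7.27 to 9.53% in Monocyte. Nothing states that replicates came from separate animals, so a p-value measures only the spread between these samples.

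Bulk counts were fitted with edgeR 4.0.16 (robust quasi-likelihood, TMM scaling, genes kept by filterByExpr) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The fit gives no standard error (SE), so the absolute log2 fold change over the square root of the F statistic was used. It is approximate, above all for genes near 0 in a group. TAM, MTM and Monocyte were fitted together in 9 libraries, the dendritic cell comparisons in 13 libraries with DC1 and DC2 added, and the genotype comparison in its 4 libraries. Gene lists written before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry; lists of fewer than 5 tested genes were left out. With an estimated correlation 1 of 15 called lists held for TAM against MTM, 2 of 12 for TAM against Monocyte, 3 of 15 for MTM against Monocyte, 1 of 13 for DC1 against DC2, 3 of 17 for TAM against DC1 and 0 of 11 for the genotype labels. fry called 14, 14, 15, 8, 14 and 0 lists in the same order. Overlaps used Fisher's exact test over the genes tested in both fits, one-sided with DC1 against DC2 and two-sided with the genotype labels. DESeq2 1.42.0 served as the second tool.

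The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with the largest increase and the 8 with the largest decrease (4 each for MTM against Monocyte and TAM against DC1). They had to pass the test, reach 20 CPM in the higher group and have every library of a group above every library of the other. Predicted, RIKEN and small RNA genes and immunoglobulin and T cell receptor segments were left out. The rule also took 11 lineage genes, up to 4 members of each list, the single-cell genes with interval bounds farthest from 1 at 50 or more UMIs, and 24 fixed T cell genes. Naming from the lists only members that passed the test was decided after the data were seen, while the largest changes and the lineage genes are given in full, except for 2 genes that are not reported here and have no row among the alternatives. Fold bounds for a group at 0 put 3 counts over that group.

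Cells with at least 500 genes and under 10% mitochondrial UMIs were kept from 509 Irf8FL and 1643 Cre_Irf8FL barcodes. Scrublet removed 9 and 7 doublets, 56 and 87 barcodes had too few genes, and 9 and 25 had too many mitochondrial UMIs. Cells were clustered in scanpy 1.11.5 on 2000 variable genes without T cell receptor segments, 20 components and 15 neighbours, with Leiden at resolution 0.8, giving 12 clusters. A cluster was named when its 20 leading genes held at least 3 markers of a fixed list and its 10 leading genes held any. Leading genes were ranked by their fold over the other clusters, with 20 CPM added to both sides. This naming rule and the pattern that finds receptor segments were settled after an exploratory clustering run. Shares have exact binomial intervals and ratios of summed UMIs exact conditional intervals, both 95%, which cover counting error only, as do floors. List ratios used genes with at least 20 UMIs, added 0.5 to each count and were set against 10000 random lists drawn from 10 bins of expression.

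The checks were tested on simulated data. In simulations on the measured counts, 100 genes were changed 2-fold and 100 were changed 4-fold, in 1 draw per comparison. The bulk fit recovered 22% of 2-fold and 73% of 4-fold changes for TAM against MTM, 0% and 39% for DC1 against DC2 and 11% and 71% for the genotype comparison. False calls were 2 of 97, 3 of 42 and 12 of 94 in the same order, so the last 2 exceeded the 0.05 aimed at. The measured TAM and MTM libraries gave far more calls (2713), so these rates need not hold there. The intervals of ratios covered the true value in 94.8 to 96.1% of genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.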

Results

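Antigen-presenting cells were sorted from breast tumours of female PyMT mice and profiled by bulk RNA sequencing in 17 libraries. These mice carry the polyoma middle T oncogene in the mammary epithelium. Tumour-associated macrophages (TAM), mammary tissue macrophages (MTM) and monocytes were represented by 3 libraries each, and type 1 and type 2 dendritic cells (DC1 and DC2) by 2 each. A further 2 libraries held TAM of mice with floxed Irf8 (Irf8FL_TAM). Another 2 held TAM of floxed mice that also carried CD11c-Cre (labelled CD11cCre_Irf8FL_TAM). CD8 T cells from tumours of Irf8FL mice and of Irf8FL mice that also carried a Cre with a driver other than CD11c (Cre_Irf8FL here) were sequenced as single cells, 1 library per genotype. Expression is given as CPM. In the bulk libraries, counts were scaled to the library total after TMM scaling, and in the single cells to the total of the cells compared. Before TMM scaling, 1 CPM stood for 23.7 to 64.7 counts in the bulk libraries. The means before it were 51.2 counts in TAM, 52.1 in MTM and 49.6 in Monocyte. They were 28.0 in DC1, 26.3 in DC2, 57.9 in Irf8FL_TAM and 54.5 in CD11cCre_Irf8FL_TAM. TMM scaling changed these numbers, and 35953 counts of Irf8 in TAM replicate 1 stood at 894 CPM. After filtering, 440 Irf8FL and 1530 Cre_Irf8FL cells remained, with medians of 6352 and 6216 unique molecular identifiers (UMIs) per cell. Values per group are CPM, mean ± SD over the libraries of that group.

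Irf8 encodes a transcription factor needed for type 1 dendritic cell development and used in monocyte and macrophage programmes (ID 15900, chromosome 8, 120736358 to 120756694, mm10). The libraries labelled CD11cCre_Irf8FL_TAM held 1311 and 1162 CPM of Irf8, above both Irf8FL_TAM libraries at 459 and 575 CPM. The counts of the targeted gene were thus not lower under the Cre label. Counts per gene cannot check the deletion of an exon, and every direction given for this genotype is a direction between labels. Among the other cells, DC1 held the most Irf8 with 3629 and 5264 CPM. TAM followed with 894, 1051 and 1049 CPM, MTM with 473, 720 and 653 CPM, and Monocyte with 387, 742 and 504 CPM. DC2 held 322 and 45.5 CPM.

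**Figure D1:**
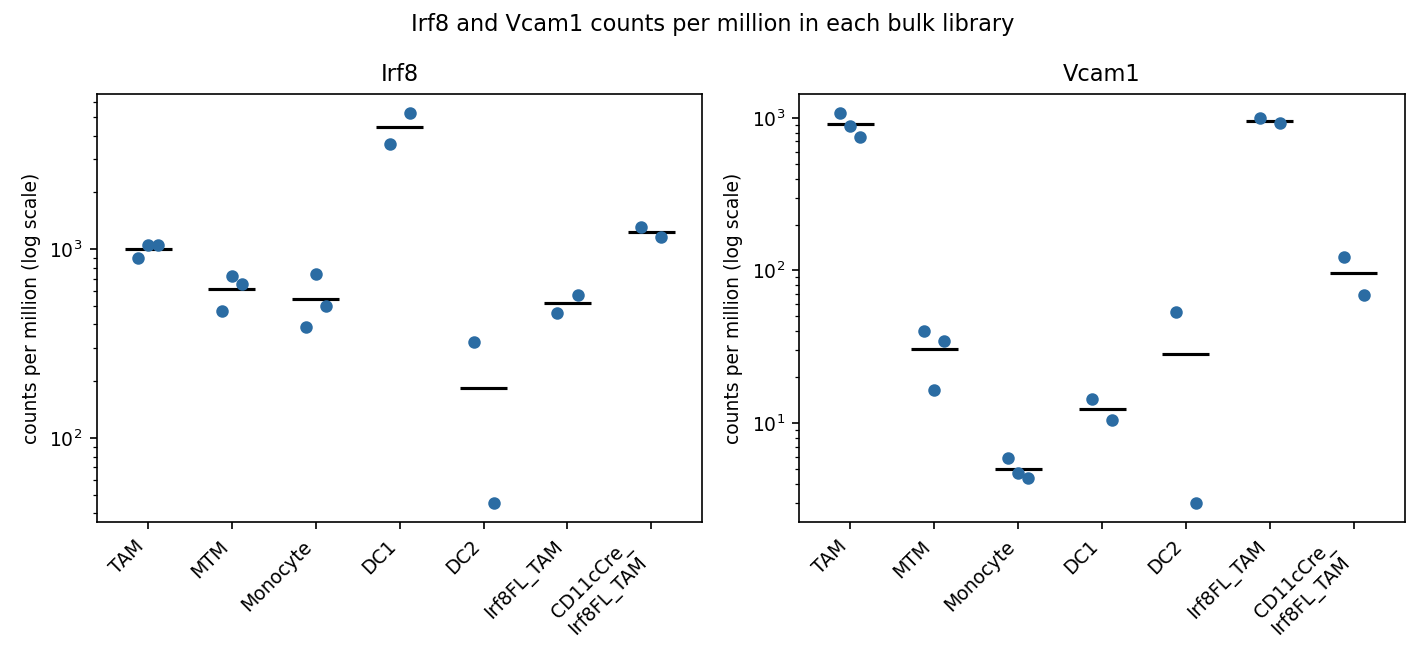
CPM of Irf8 and Vcam1 on log axes in the 17 bulk libraries of 7 groups; points are libraries and lines are group means. Irf8 lay at 1311 and 1162 CPM in the libraries labelled CD11cCre_Irf8FL_TAM against 459 and 575 CPM in Irf8FL_TAM, while mean Vcam1 was 96.1 CPM against 959 CPM.

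The first comparison set the 2 macrophage populations of PyMT tumours against each other. TAM were far richer in Vcam1, an adhesion molecule that binds leukocyte integrins (ID 22329, chromosome 3, 116110020 to 116129688), with 906 ± 161 CPM against 30.5 ± 12.4 CPM in MTM (n = 3 each; log2 fold change 4.89, SE 0.336, adjusted p = 1.08e-05). MTM held more monocyte transcripts, the only list call that held with an estimated correlation. Calls of more MHC class II transcripts in TAM and of more matrix, hypoxia and cell cycle transcripts in MTM were lost with it. Among the genes higher in TAM, the largest changes were those of Clec9a, a dendritic cell receptor for dead cells (6.23; 42.8 ± 8.23 against 0.559 ± 0.411 CPM), and of the milk protein gene Lalba (5.71). The plasmacytoid cell lectin Siglech (5.14; 124 ± 14.4 against 3.48 CPM), Igfbp2 (5.07), Vcam1, the MHC class Ib gene H2-M2 (4.88), the integrin chain Itgb8 (4.65) and the iron-binding protein Ltf (4.35) followed. Among the genes lower in TAM, they were those of Retnla, an alternative activation marker (−10.87; 0.978 ± 0.525 against 1805 ± 1424 CPM), and of the retinoic acid enzyme Aldh1a2 (−7.91). They were followed by fibronectin Fn1 (−7.50; 12.2 ± 3.21 against 2205 ± 1218 CPM), the lysozyme Lyz1 (−7.38), Cspg4 (−7.19), the coagulation factors F7 (−7.07) and F10 (−6.93), and Ryr1 (−6.29). These 16 genes had adjusted p-values from 4.55e-06 to 0.0156 in edgeR's quasi-likelihood test.

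**Figure D2:**
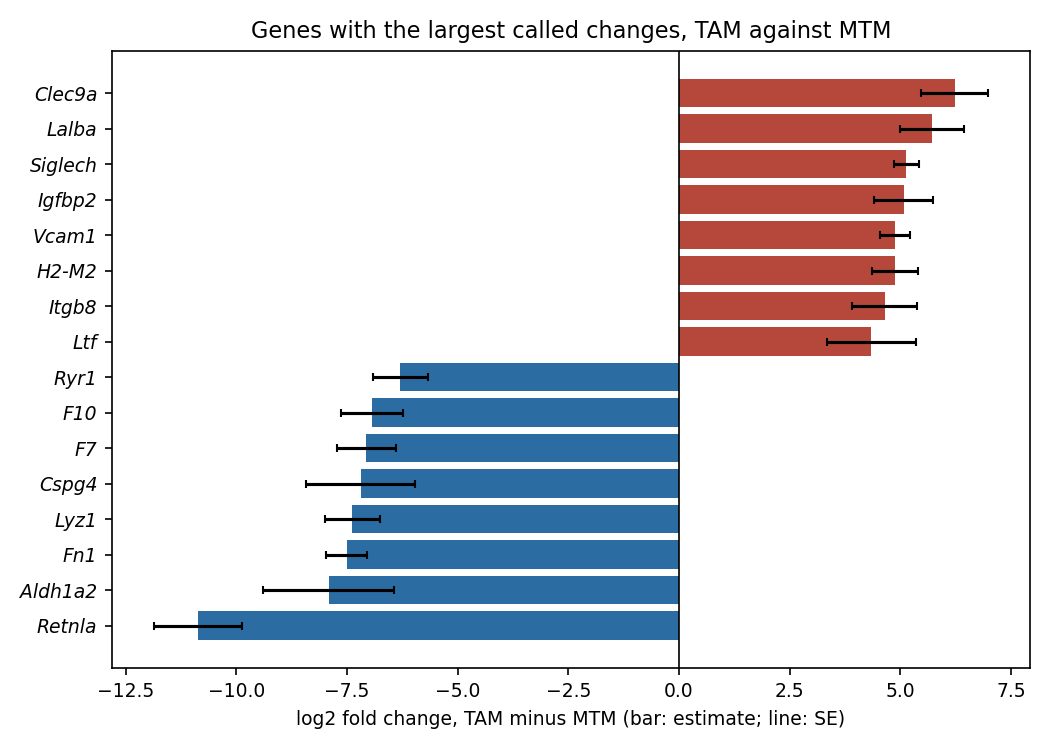
Log2 fold change, TAM minus MTM, of the 8 genes with the largest increase and the 8 with the largest decrease by the rule for named genes. Bars are edgeR estimates and lines their approximate standard errors, derived from the F statistic (3 libraries per group). The values ran from −10.87 for Retnla to 6.23 for Clec9a.

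Of the lineage genes, the integrin chain Itgam (CD11b) was lower in TAM (−3.28; 98.5 ± 22.4 against 953 ± 215 CPM, adjusted p = 1.4e-05), as was Ly6c2 (−4.33). H2-Ab1 was higher (1.60, adjusted p = 0.000158). Irf8 (0.69, SE 0.239, adjusted p = 0.065, 0.0202 to 0.426 over the alternatives), Mrc1 (−0.86), Itgax (0.34), Adgre1 (0.32), Xcr1 (0.87) and Sirpa (−0.46) did not pass. In the MHC class II list 9 of 11 genes rose and 1 fell (10 and 1 adjusted over the list alone), led by H2-Oa (2.19), H2-Ab1, H2-Aa (1.60) and H2-Eb1 (1.55). The list's adjusted p was 2.03e-08, and adjusted p = 0.178 with an estimated correlation. In the monocyte list 8 of 14 genes fell (9 over the list alone), among them Fn1, the calcium-binding protein S100a4 (−5.64) and Chil3 (−4.67). This was the only list whose call held with an estimated correlation (adjusted p = 7.84e-15, and adjusted p = 0.015 with an estimated correlation). Cell cycle genes fell in 19 of 25 cases (22 over the list alone), with the mitotic genes Bub1 and Ccna2 both at −2.49 (list adjusted p = 5.59e-13, and adjusted p = 0.226 with an estimated correlation). Of the hypoxia and glycolysis genes 16 of 23 fell (1 higher and 18 lower over the list alone), among them Vegfa (−2.45) and the glucose transporter Slc2a1 (−1.66; list adjusted p = 1.44e-09, and adjusted p = 0.178 with an estimated correlation).

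Further lists were called lower in TAM at the preset correlation only, with many of their genes not passing. Tissue-resident macrophage genes fell in 7 of 17 cases and rose in 1 (2 higher and 10 lower over the list alone), with the hyaluronan receptor Lyve1 (−6.49), the scavenger receptor Cd163 (−5.11) and F13a1 (−4.38). The list's adjusted p was 0.00115, and adjusted p = 0.508 with an estimated correlation. Matrix remodelling genes fell in 6 of 19 cases and rose in 3 (5 and 12 over the list alone), with Mmp8 (−6.54), Mmp19 (−6.28) and Mmp9 (−5.81, list adjusted p = 9.38e-05, and adjusted p = 0.226 with an estimated correlation). Lipid-associated macrophage genes fell in 4 of 13 cases, with Gpnmb (−5.56), Spp1 (−3.67) and Fabp5 (−2.30), while Cd63 rose (1.42; 2 higher and 6 lower over the list alone, list adjusted p = 0.0434, and adjusted p = 0.523 with an estimated correlation). Chemokine genes fell in 9 of 22 cases and rose in 1, with Ccl24 (−7.80), Cxcl3 (−4.67) and Ccl2 (−2.78; 4 and 12 over the list alone, list adjusted p = 0.0194, and adjusted p = 0.266 with an estimated correlation). Inflammatory cytokine genes fell in 5 of 16 cases and rose in 1, with Clec4e (−6.13) and Ptgs2 (−3.16; 1 and 8 over the list alone, list adjusted p = 0.00135, and adjusted p = 0.523 with an estimated correlation). DC2 markers fell in 6 of 12 cases and rose in 2, with Cd209a (−5.92) and Irf4 (−4.70; 2 and 9 over the list alone, list adjusted p = 0.0234, and adjusted p = 0.226 with an estimated correlation). Of the cholesterol efflux genes 6 of 19 fell and 1 rose, with Pltp (−4.50; 2 and 9 over the list alone, list adjusted p = 0.0412, and adjusted p = 0.226 with an estimated correlation). The complement genes C1qa (1.06), C1qc (0.94) and C1qb (0.90) rose and the efferocytosis receptor Mertk fell (−1.01). The macrophage core list as a whole, 3 up and 2 down of 12, was not called (adjusted p = 0.647). DC1 markers split into 4 up, with Clec9a and Cadm1 (1.56), and 4 down, with Ifi205 (−2.27) and Naaa (−1.97). They were not called (adjusted p = 0.647).

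Lists for T cell ligands (2 up with Cd86 at 1.04, 3 down with Cd274 at −1.81, of 21; adjusted p = 0.475), interferon response (2 up and 5 down of 30; 0.271), MHC class I presentation (3 up of 16; 0.057) and known IRF8 targets (2 up and 2 down of 10; 0.647) were not called. The medians of the interferon, T cell ligand and mature dendritic cell lists changed sign under upper-quartile scaling, which moved all genes. The median, mean and test of a list differed in sign for phagocytosis (median 0.27, mean −0.10, test down), mature dendritic cells (−0.05, −0.43, up), known IRF8 targets (0.06, −0.16, up) and T cells (0.58, −0.09, up). Beside these groups, markers of other cells also differed between the populations. Mammary epithelial genes rose in 11 of 19 cases (13 over the list alone), with Lalba, Wap (3.76) and Csn3 (3.05, list adjusted p = 9.4e-08, and adjusted p = 0.269 with an estimated correlation). Neutrophil genes fell in 8 of 12, with Retnlg (−6.35) and with Ly6g, at 0 in TAM and at least 23.6-fold lower, while Ltf rose (1 and 9 over the list alone, adjusted p = 3.24e-11, and adjusted p = 0.178 with an estimated correlation). Dissociation stress genes fell in 5 of 16 cases (1 higher and 7 lower over the list alone, adjusted p = 0.0194, and adjusted p = 0.548 with an estimated correlation). The plasmacytoid list was called higher on 1 rise, Siglech, and 1 fall, Runx2 at −1.85, of 7 (the same counts over the list alone, adjusted p = 0.045, and adjusted p = 0.226 with an estimated correlation).

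Genes with near-identical copies in the genome (the Cd209 family, Klra17, Sirpb1a, Pilrb1, Ly6c2, Lyz1, Ccl12 and the H2- genes) are uncertain in identity throughout, since reads can be shared among copies. In all, 1098 genes were higher and 1615 lower in TAM than in MTM among 14088 tested, and the libraries of the 2 groups did not overlap in 46.2% of genes, where chance gives 10%. Under upper-quartile scaling, which shifted the median of all genes by 0.15, the split was 1672 higher and 1169 lower. With the level of mammary epithelial genes as a covariate, chosen after the data were seen, it was 322 and 630. That level, a mean of log2 CPM over the list, was 5.93, 6.36 and 7.30 in TAM and 4.89, 4.82 and 4.67 in MTM. The covariate thus largely follows the group, and calls lost with it cannot be read as epithelial. The genes higher in TAM than in MTM numbered 708 without TAM replicate 1, 504 without TAM replicate 3, and 578, 603 and 472 without MTM replicates 1, 2 and 3. The genes lower in TAM than in MTM numbered 1030 without TAM replicate 1 and 898 without MTM replicate 3.

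Against monocytes of the same tumour model, TAM held more MHC class II and less of the monocyte transcripts. Calls of more macrophage core, complement and cell cycle transcripts were lost with an estimated correlation. The largest increases were those of Siglech (10.26; 124 ± 14.4 against 0.0987 CPM), the protease Capn3 (9.19), H2-M2 (8.67) and the lectin Cd207 (8.65). The transporter Slco2b1 (8.14), Tlr12 (7.83), Lag3 (7.82) and Lrrc3 (7.71) followed, and Vcam1 rose by 7.48. Cyp2ab1 had no count in any TAM library and was at least 1157-fold lower, with the floor of 3 counts taken over the group. Other large decreases were those of Tarm1 (−12.00), Chil3 (−11.31; 1.88 ± 0.426 against 4716 ± 1439 CPM), Mmp8 (−11.25), Bmx (−10.43), Serpinb10 (−9.86) and Pi16 (−9.81). These 15 genes had an adjusted p of 7.89e-05 or lower (edgeR quasi-likelihood). Irf8 was higher in TAM (0.85, adjusted p = 0.0182; 0.00293 to 0.281 over the alternatives), as were H2-Ab1 (4.90), Itgax (3.66), Mrc1 (2.79) and Adgre1 (1.45). Ly6c2 (−9.78), Itgam (−3.35) and Sirpa (−0.59) were lower, and Xcr1 (0.81) did not pass.

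All 14 monocyte genes fell (14 over the list alone, adjusted p = 1.92e-35, and adjusted p = 0.00155 with an estimated correlation). Of 11 MHC class II genes 10 rose with 1 falling (10 and 1 over the list alone), with H2-Eb1 at 5.74 and H2-Aa at 4.79 (list adjusted p = 7.83e-24, and adjusted p = 0.0263 with an estimated correlation). The following calls did not hold with an estimated correlation. Of 25 cell cycle genes 23 rose (23 over the list alone), with Tk1 (3.12) and Cdk1 (2.93, list adjusted p = 3.7e-10, and adjusted p = 0.371 with an estimated correlation). Macrophage core genes rose in 6 of 12 cases and fell in 1 (the same over the list alone), with C1qa (6.50), C1qc (6.25), C1qb (5.80) and Mertk (2.63, list adjusted p = 6.54e-06, and adjusted p = 0.094 with an estimated correlation). Phagocytosis genes rose in 12 of 21 cases and fell in 4 (13 and 4 over the list alone, adjusted p = 0.00157, and adjusted p = 0.28 with an estimated correlation). Lipid-associated genes rose in 6 of 13 and fell in 3 (the same over the list alone), with Cd63 (5.05) and Apoe (3.03, list adjusted p = 0.00205, and adjusted p = 0.385 with an estimated correlation). Tissue-resident genes rose in 9 of 17 and fell in 3 (10 and 3 over the list alone, adjusted p = 0.0436, and adjusted p = 0.761 with an estimated correlation). DC1 markers rose in 6 of 13 and fell in 3 (7 and 3 over the list alone, adjusted p = 0.0494, and adjusted p = 0.33 with an estimated correlation). Interferon genes fell in 16 of 30 cases and rose in 2 (the same over the list alone), with Oas3 (−2.93) against Ifi44 (2.76, list adjusted p = 0.00206, and adjusted p = 0.698 with an estimated correlation). Hypoxia genes fell in 9 of 23 and rose in 2 (2 and 10 over the list alone, adjusted p = 0.0228, and adjusted p = 0.623 with an estimated correlation).

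Neutrophil genes fell in 11 of 12 cases (11 over the list alone), with Ly6g at 0 in every TAM library (adjusted p = 9.23e-13, and adjusted p = 0.132 with an estimated correlation). The plasmacytoid list, 2 up and 1 down of 7 (the same over the list alone), was called higher (adjusted p = 0.0424, and adjusted p = 0.26 with an estimated correlation). Median, mean and test differed in sign for conventional dendritic cell genes (0.04, −1.61, down), known IRF8 targets (−0.31, 0.17, up) and cholesterol efflux (−0.32, −0.05, up). Of 14088 genes, 2323 were higher and 2516 lower in TAM, and 46.7% did not overlap between the groups, where chance gives 10%. Upper-quartile scaling shifted the median of all genes by 0.24 and gave 3002 higher and 1987 lower.

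MTM also differed from monocytes in MHC class II, macrophage core and monocyte transcripts, and in every gene of the cell cycle list. Retnla (11.58; 1805 ± 1424 against 0.593 CPM), the collagen gene Col14a1 (8.09), the lectin Mgl2 (7.72) and Slco2b1 (7.63) rose most. Arhgef37 (−6.71), the neutrophil antigen Cd177 (−6.64), Chil3 (−6.64) and the sphingosine receptor S1pr5 (−6.46) fell most. These 8 had adjusted p-values of 0.000245 or lower (edgeR quasi-likelihood). Every one of the 25 cell cycle genes rose (25 over the list alone), with Tpx2 (4.88), Cdk1 (4.46), Ccna2 (4.39) and Top2a (4.37, list adjusted p = 5.94e-39, and adjusted p = 0.0638 with an estimated correlation). Mrc1 (3.64), Itgax (3.32), H2-Ab1 (3.30), Vcam1 (2.59) and Adgre1 (1.13) were higher and Ly6c2 (−5.45) lower. Irf8 (0.16, adjusted p = 0.677), Itgam (−0.07), Xcr1 (−0.05) and Sirpa (−0.12) did not pass. Of the calls that held with an estimated correlation, 12 of 14 monocyte genes fell (12 over the list alone, adjusted p = 2.93e-28, and adjusted p = 0.00057 with an estimated correlation). MHC class II genes rose in 10 of 11 cases (10 over the list alone, adjusted p = 1.2e-19, and adjusted p = 0.0444 with an estimated correlation) and macrophage core genes in 6 of 12 (7 over the list alone), with C1qa at 5.43 (list adjusted p = 8.73e-09, and adjusted p = 0.0444 with an estimated correlation). Lipid-associated genes rose in 10 of 13 cases (11 over the list alone, adjusted p = 7.83e-11, and adjusted p = 0.0658 with an estimated correlation). Tissue-resident genes rose in 11 of 17 with 1 falling (15 and 1 over the list alone, adjusted p = 5.38e-07, and adjusted p = 0.223 with an estimated correlation). Phagocytosis genes rose in 10 of 21 with 1 falling (11 and 3 over the list alone, adjusted p = 3.46e-07, and adjusted p = 0.0658 with an estimated correlation) and chemokine genes in 8 of 22 (9 over the list alone, adjusted p = 7.71e-05, and adjusted p = 0.0905 with an estimated correlation).

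Smaller calls in this comparison were cholesterol efflux (7 up and 1 down of 19, the same over the list alone, adjusted p = 0.0318, and adjusted p = 0.207 with an estimated correlation) and matrix remodelling (8 up and 3 down of 19, 9 and 4 over the list alone, adjusted p = 0.0297, and adjusted p = 0.447 with an estimated correlation). DC1 markers (4 up and 1 down of 13, 4 and 2 over the list alone, adjusted p = 0.00992, and adjusted p = 0.171 with an estimated correlation) were called higher and interferon genes (1 up and 9 down of 30, the same over the list alone, adjusted p = 0.00477, and adjusted p = 0.601 with an estimated correlation) lower. Of the markers of other cells, neutrophil genes fell in 6 of 12 cases (10 over the list alone, adjusted p = 1.52e-05, and adjusted p = 0.207 with an estimated correlation). Mammary epithelial genes fell in 3 of 19 (3 over the list alone), with Lalba at −2.91 (list adjusted p = 0.0196, and adjusted p = 0.632 with an estimated correlation) and endothelial genes in 2 of 9 with 1 rising (1 and 3 over the list alone, adjusted p = 0.0407, and adjusted p = 0.189 with an estimated correlation). Median, mean and test differed in sign for known IRF8 targets (0.12, 0.33, down), T cell ligands (−0.07, 0.32, up), inflammatory cytokines (−0.18, 0.11, up), dissociation stress (0.03, 0.00, down) and plasmacytoid genes (−0.23, 1.11, up). Of 14088 genes, 1756 were higher and 1412 lower in MTM, 38.9% without overlap where chance gives 10%. Without MTM replicate 2, 917 were lower.

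The 2 dendritic cell types were separated by their known markers, although the DC2 libraries differed from each other (correlation of log CPM 0.8855). Mammary epithelial genes summed to 8653 and 19930 CPM in DC2 replicates 1 and 2 against 4763 and 1801 CPM in DC1, and MHC class II genes to 58890 and 22440 CPM in DC2, so folds between the types also carry this difference. DC1 held 911 ± 167 CPM of the chemokine receptor Xcr1 (ID 23832, chromosome 9, 123852315 to 123862029) against 1.47 ± 1.48 CPM in DC2 (n = 2 each; log2 fold change 9.29, SE 1.59, adjusted p = 0.00447). Irf8 was higher by 4.63 (adjusted p = 0.00286; 4.6e-12 to 0.228 over the alternatives). Gpr33 (9.98), Xcr1, Gcsam (8.75), Gpr141b (8.17), Sema4f (7.31), Cyp8b1 (7.25), Clnk (7.19) and Clec9a (6.57) rose most in DC1. The lectins Cd209d (−9.15) and Cd209a (−8.53), F10 (−8.09), Sirpb1a (−7.09), Pilrb1 (−6.86), Rasgrp1 (−6.33), the lipid transfer protein Pltp (−6.24) and the interleukin 33 receptor Il1rl1 (−6.23) fell most. Adjusted p-values of these 16 genes reached 0.0348. Sirpa (−4.41), Itgam (−4.46), Mrc1 (−5.45) and Adgre1 (−2.18, adjusted p = 0.0299) were lower in DC1. Vcam1 (−1.18), H2-Ab1 (1.18), Ly6c2 (−0.26) and Itgax (0.27) did not pass.

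All 14 DC1 markers rose (14 over the list alone), with the double-stranded RNA sensor Tlr3 at 5.02, and this call held (adjusted p = 8.17e-31, and adjusted p = 0.00472 with an estimated correlation). DC2 markers fell in 8 of 12 cases and rose in 1 (1 and 10 over the list alone), with Mgl2 (−5.96, list adjusted p = 8.3e-13, and adjusted p = 0.186 with an estimated correlation). Macrophage core genes fell in 11 of 12 (11 over the list alone), with Mertk (−4.51, list adjusted p = 1.56e-08, and adjusted p = 0.358 with an estimated correlation). MHC class I genes rose in 6 of 16 cases (9 over the list alone), among them the immunoproteasome subunit Psmb9 (2.85) and the peptide transporter Tap1 (2.01, list adjusted p = 2.36e-09, and adjusted p = 0.358 with an estimated correlation). MHC class II genes rose in 3 of 11 (7 over the list alone), with H2-Aa at 1.28 (list adjusted p = 0.000945, and adjusted p = 0.504 with an estimated correlation). Cell cycle genes rose in 6 of 25 cases (19 over the list alone, adjusted p = 2.18e-09, and adjusted p = 0.415 with an estimated correlation). Conventional dendritic cell genes rose in 2 of 10 (4 over the list alone), Btla (3.94) and Flt3 (2.91, list adjusted p = 0.00269, and adjusted p = 0.415 with an estimated correlation). Called lower were genes of tissue-resident macrophages (6 down of 17, 9 over the list alone, adjusted p = 0.00011, and adjusted p = 0.415 with an estimated correlation) and phagocytosis (1 up and 8 down of 21, 2 and 14 over the list alone, adjusted p = 0.000164, and adjusted p = 0.504 with an estimated correlation). Matrix remodelling (1 up and 5 down of 19, 1 and 9 over the list alone, adjusted p = 0.000281, and adjusted p = 0.415 with an estimated correlation) and chemokines (3 down of 22, 5 over the list alone, adjusted p = 0.00289, and adjusted p = 0.504 with an estimated correlation) were called lower. So were dissociation stress genes (6 of 16, 7 over the list alone, adjusted p = 0.00013, and adjusted p = 0.415 with an estimated correlation) and mammary epithelial genes, where Epcam fell by 2.57 (1 of 19; 1 higher and 9 lower over the list alone, adjusted p = 0.000191, and adjusted p = 0.504 with an estimated correlation).

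The fit of 13 libraries called 615 genes higher and 982 lower in DC1 among 15499, and 48.0% did not overlap between the 2 groups of 2, where chance gives 33.3%. A fit of the 4 dendritic cell libraries alone called 0 genes with edgeR, with 2089 of 14018 at an unadjusted p below 0.05. DESeq2 called 403 higher and 905 lower in it. DC1 replicate 1 had a preparation text of its own, and without it the genes higher in DC1 than in DC2 numbered 617 and the genes lower in DC1 than in DC2 numbered 1232. Without DC1 replicate 2 the counts were 215 and 214. Without DC2 replicate 2 they were 268 and 637, and without DC2 replicate 1, 1639 genes were higher. Median, mean and test differed in sign for mature dendritic cells (−0.48, −0.27, up), B cells (−1.31, −0.59, up), NK cells (0.04, −0.13, down) and neutrophils (0.06, −0.27, down).

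TAM were set against DC1 to place them beside the cells with the most Irf8. Their preparation texts differ, so protocol and cell type cannot be told apart here. The macrophage genes separated them most, and all 12 core genes were higher in TAM (12 over the list alone), with C1qc (6.89), C1qa (6.79) and C1qb (6.75, list adjusted p = 1.46e-24, and adjusted p = 0.0404 with an estimated correlation). DC1 markers fell in 11 of 14 cases (12 over the list alone), with the integrin chain Itgae (−9.38, list adjusted p = 3.49e-19, and adjusted p = 0.0404 with an estimated correlation). Conventional dendritic cell genes fell in 8 of 10 with 1 rising (1 and 9 over the list alone), with the growth factor receptor Flt3 (−10.18, list adjusted p = 1.7e-11, and adjusted p = 0.0499 with an estimated correlation). B3galnt1, at 0 in DC1, was at least 602-fold higher in TAM, and Itga9 (8.14), Klra17 (7.98) and the chemokine Ccl12 (7.69) followed. Gcsam, Siglecg and Sema4f had no count in TAM and were at least 17670-fold, 2539-fold and 2324-fold lower, and Btla stood at 0.0249 against 419 ± 48.7 CPM (adjusted p = 3.83e-06). Irf8 was lower in TAM (−2.19, adjusted p = 0.0186; 0.000275 to 0.116 over the alternatives), as were Xcr1 (−5.98) and Ly6c2 (−3.67). Vcam1 (6.16), Adgre1 (6.12), Sirpa (5.77), Mrc1 (4.90), Itgam (3.27) and Itgax (1.41, adjusted p = 0.0485) were higher and H2-Ab1 (0.84) did not pass. In total 1367 genes were higher and 1338 lower among 15499, 47.5% without overlap where chance gives 20%. Without DC1 replicate 2 these counts were 841 and 668, and without TAM replicate 2, 872 genes were lower.

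Other lists differed between TAM and DC1, all losing their call with an estimated correlation. Phagocytosis genes rose in 15 of 21 cases and fell in 2 (16 and 2 over the list alone, adjusted p = 1.22e-15, and adjusted p = 0.153 with an estimated correlation). Cell cycle genes fell in 16 of 25 (23 over the list alone, adjusted p = 3.02e-11, and adjusted p = 0.365 with an estimated correlation). Lipid-associated genes (7 up and 1 down of 13, 7 and 2 over the list alone, adjusted p = 5.6e-05, and adjusted p = 0.153 with an estimated correlation), with Apoe at 6.17, and chemokines (11 up and 3 down of 22, 14 and 3 over the list alone, adjusted p = 0.000135, and adjusted p = 0.398 with an estimated correlation) were higher in TAM. Also higher were inflammatory cytokines (8 up and 2 down of 16, 10 and 2 over the list alone, adjusted p = 0.000436, and adjusted p = 0.517 with an estimated correlation) and matrix remodelling (9 up and 2 down of 19, 9 and 4 over the list alone, adjusted p = 9.97e-05, and adjusted p = 0.365 with an estimated correlation). Cholesterol efflux (10 up and 4 down of 19, the same over the list alone, adjusted p = 0.0166, and adjusted p = 0.43 with an estimated correlation) and dissociation stress (7 up and 1 down of 16, 9 and 1 over the list alone, adjusted p = 0.000737, and adjusted p = 0.43 with an estimated correlation) were higher as well. DC2 markers (6 up and 2 down of 12, 6 and 3 over the list alone, adjusted p = 0.000753, and adjusted p = 0.398 with an estimated correlation) and tissue-resident genes (5 up and 1 down of 17, 6 and 2 over the list alone, adjusted p = 0.0108, and adjusted p = 0.553 with an estimated correlation) rose as well. Mature dendritic cell genes fell in 7 of 12 cases (9 over the list alone), with Ccr7 (−6.40, list adjusted p = 8.37e-05, and adjusted p = 0.365 with an estimated correlation). MHC class I genes fell in 6 of 16 (6 over the list alone, adjusted p = 0.0399, and adjusted p = 0.701 with an estimated correlation) and NK cell genes in 2 of 9 (3 over the list alone, adjusted p = 0.0128, and adjusted p = 0.43 with an estimated correlation). The mammary epithelial list was called higher with 0 of 19 genes passing (0 over the list alone, adjusted p = 0.0417, and adjusted p = 0.741 with an estimated correlation). Median, mean and test differed in sign for known IRF8 targets (−0.92, 0.55, up) and neutrophils (−0.01, 0.47, up).

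Whether TAM and MTM differ in the genes that separate DC1 and DC2 was asked with the planned 4-library calls, which shared 0 genes because that fit called none. With the calls of the 13-library fit, whose fit also holds the TAM and MTM libraries, 98 genes were higher in both TAM and DC1 (47.1 expected for independent lists; odds ratio 2.42, 95% interval 1.91 to 3.04, Fisher's exact one-sided p = 1.46e-12) and 226 were lower in both (112 expected; odds ratio 2.54, 2.16 to 2.99, exact p = 4.78e-27). The set test took the 200 genes most strongly higher and the 200 lower in DC1 from the same 13-library fit, a choice made after the 4-library result was seen. The DC1-higher genes had a median log2 fold change of 0.28 between TAM and MTM (camera adjusted p = 0.00358, and adjusted p = 0.15 with an estimated correlation), and the DC1-lower genes −0.60 (adjusted p = 2.1e-18, and adjusted p = 0.0114 with an estimated correlation).

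The genotype comparison asked what a floxed Irf8 gene with CD11c-Cre changes in TAM. The Irf8 counts themselves were higher in the libraries labelled CD11cCre_Irf8FL_TAM (1236 ± 106 against 517 ± 82.3 CPM, n = 2 each; log2 fold change 1.21, SE 0.239). The difference did not pass the test (adjusted p = 0.126; 9e-06 to 1 over the alternatives). Vcam1 was lower in the libraries labelled CD11cCre_Irf8FL_TAM, with 96.1 ± 37.6 against 959 ± 56.5 CPM (−3.37, SE 0.343, adjusted p = 0.0263; 1.23e-22 to 0.162 over the alternatives). Fn1 (ID 14268, chromosome 1, 71585473 to 71653280) was higher in them, with 243 ± 51.1 against 2.76 CPM (6.40, adjusted p = 0.0135). The other genes with the largest increases under that label were the integrin chain Itgad (6.48), the B cell adaptor Bank1 (5.92), Nxpe5 (4.98), the protease Htra3 (4.71), the GTPase Gbp2b (4.56), the macrophage growth factor Csf1 (3.93) and the adhesion receptor Adgre4 (3.73). The other large decreases were those of the proteoglycan Dcn (−4.57), the receptor Klra17 (−3.60), the nuclease Dnase1l3 (−3.08), Enpp4 (−3.06), the interleukin 7 receptor Il7r (−2.93), the peptidase Dpp4 (−2.78) and the checkpoint receptor gene Pdcd1 (−2.74). Xcr1 was lower (−3.87, adjusted p = 0.0434). Itgam (1.86), Mrc1 (0.85), H2-Ab1 (−1.47), Ly6c2 (0.58), Itgax (0.36), Adgre1 (0.34) and Sirpa (0.78) did not pass.

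No list call in this comparison held with an estimated correlation. In the libraries labelled CD11cCre_Irf8FL_TAM, DC1 markers were called lower, Clec9a (−4.21) and Xcr1 passing among 13 (1 higher and 5 lower over the list alone, adjusted p = 1.63e-07, and adjusted p = 0.529 with an estimated correlation). The interferon list (0 of 30 passing, 9 lower over the list alone, adjusted p = 8.04e-09, and adjusted p = 0.544 with an estimated correlation) and the MHC class II list (0 of 11, and 0 over the list alone, adjusted p = 2.18e-06, and adjusted p = 0.544 with an estimated correlation) were called lower. So was the MHC class I list (0 of 16, and 0 over the list alone, adjusted p = 0.0458, and adjusted p = 0.544 with an estimated correlation). Called higher were lipid-associated genes (0 of 13, 4 over the list alone, adjusted p = 3.46e-06, and adjusted p = 0.529 with an estimated correlation) and monocyte genes (Fn1 of 14, 2 over the list alone, adjusted p = 0.000268, and adjusted p = 0.529 with an estimated correlation). So were hypoxia (0 of 23, and 0 over the list alone, adjusted p = 6.02e-06, and adjusted p = 0.544 with an estimated correlation) and cholesterol efflux (Pltp at 2.54 of 19, 2 over the list alone, adjusted p = 0.00302, and adjusted p = 0.544 with an estimated correlation). Matrix remodelling was called higher (Fn1 up and Mmp2 at −2.73 of 19, 5 up and 1 down over the list alone, adjusted p = 0.0175, and adjusted p = 0.544 with an estimated correlation). The chemokine Cxcl14 rose (1.94) in a list that was not called. Mammary epithelial genes were called lower, Wfdc2 (−1.89) passing among 18 (6 over the list alone, adjusted p = 2.72e-09, and adjusted p = 0.544 with an estimated correlation). Dissociation stress genes were called higher (0 of 16, and 0 over the list alone, adjusted p = 0.0042, and adjusted p = 0.568 with an estimated correlation). The median and mean of the phagocytosis list differed in sign (−0.04, 0.20, test up).

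edgeR called 39 genes higher and 25 lower in the libraries labelled CD11cCre_Irf8FL_TAM among 14676, with 1484 at an unadjusted p below 0.05 and 40.1% without overlap, where chance gives 33.3%. DESeq2 called 334 and 323. Without Irf8FL_TAM replicate 1 or replicate 2 edgeR called 0 genes, with 664 and 849 at an unadjusted p below 0.05. Without CD11cCre_Irf8FL_TAM replicate 1 it called 301 higher and 360 lower, and without replicate 2, 473 and 1041. Each of these fits leaves 1 library under a label, so its spread comes only from the 2 libraries of the other label, and the counts reflect which 2 those are.

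Genes that separate TAM from MTM moved the opposite way between these labels. The mammary epithelial list, also called higher in TAM, had a median of −0.86 between them, with only Wfdc2 passing. Both calls of this list were lost with an estimated correlation. The 200 genes most strongly higher in TAM had a median log2 fold change of −0.50 in the libraries labelled CD11cCre_Irf8FL_TAM (159 of 200 negative, camera adjusted p = 7.77e-18, and adjusted p = 0.00684 with an estimated correlation). The 190 tested of the 200 genes lower in TAM had a median of 0.94 (163 positive, adjusted p = 8.96e-46, and adjusted p = 0.00684 with an estimated correlation). With sets chosen with the epithelial level as a covariate the medians were −0.48 and 0.76. Of the 25 genes lower under the Cre label 12 were among those higher in TAM, Vcam1, Clec9a, H2-M2, Dnase1l3, Dpp4, Mmp2, Dmbt1, Ly9, Fam20a, Enpp4, Dgat2 and Slamf7, where 1.98 were expected (odds ratio 10.8, 95% interval 4.50 to 25.8, Fisher's exact two-sided p = 1.15e-07). Of 38 genes higher under it 26 were among those lower in TAM, Fn1, Cspg4, Csf1, Pltp and Trem1 among them, where 4.31 were expected (odds ratio 17.2, 95% interval 8.37 to 37.5, Fisher's exact two-sided p = 1.48e-16). In the same direction 2 genes were shared among those higher (3.02 expected) and 1 among those lower (2.83 expected).

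**Figure D3:**
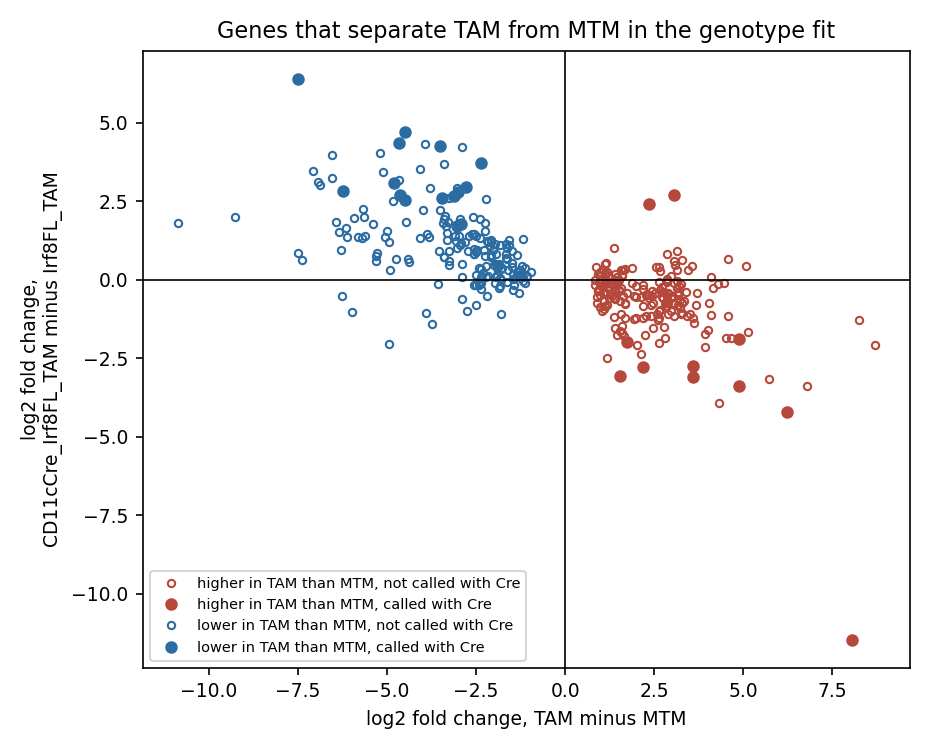
Log2 fold change of CD11cCre_Irf8FL_TAM minus Irf8FL_TAM (vertical) against that of TAM minus MTM (horizontal) for the 200 genes most strongly higher (red) and 200 lower (blue) in TAM; filled points passed the test between the genotype labels. The medians on the vertical axis were −0.50 for the red and 0.94 for the blue genes; the fitted value of Dmbt1, at 0 in both Cre-labelled libraries, is no bound on its fold change.

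Single CD8 T cells were compared between Irf8FL and the Cre_Irf8FL library. With 1 library per genotype no test was possible, and intervals cover counting error only. Of the kept cells, 78.0% in Irf8FL and 95.6% in Cre_Irf8FL carried CD3 and CD8 UMIs without Cd4. Exhausted-like cells, defined by Pdcd1, Lag3, Tigit, Tox and other fixed markers, made up 19.1% of Irf8FL cells (95% exact interval 15.5 to 23.1) against 3.20% of Cre_Irf8FL cells (2.38 to 4.21) when the marker genes were left out of the clustering, an alternative added after the data were seen. With all genes the shares were 33.4% (29.0 to 38.0) and 9.48% (8.06 to 11.1), in 2 clusters. The second of these was led by the heat shock genes Hspa1a, Hspa1b and Dnajb1 as well as Pdcd1. Naive or central memory-like cells made up 0.909% against 4.18% without the marker genes, and 1.59% against 7.39% with them, but 11.8% against 50.2% with the same number of cells per library. In the same order of libraries, innate-like cells made up 7.73% and 9.02% without marker genes (7.27% and 9.67% with them), interferon-responding cells 7.95% and 7.52% (7.27% and 9.35%), and cycling cells 7.50% and 10.8% (8.41% and 11.4%). Innate-like shares also depended on the clustering, with 18.2% and 19.5% at resolutions 0.4 and 1.2, 18.7% and 19.5% with no doublet removal and 19.8% and 20.7% with the same number of cells per library. Unnamed clusters held 25.2% of Irf8FL and 49.4% of Cre_Irf8FL cells with all genes.

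**Figure D4:**
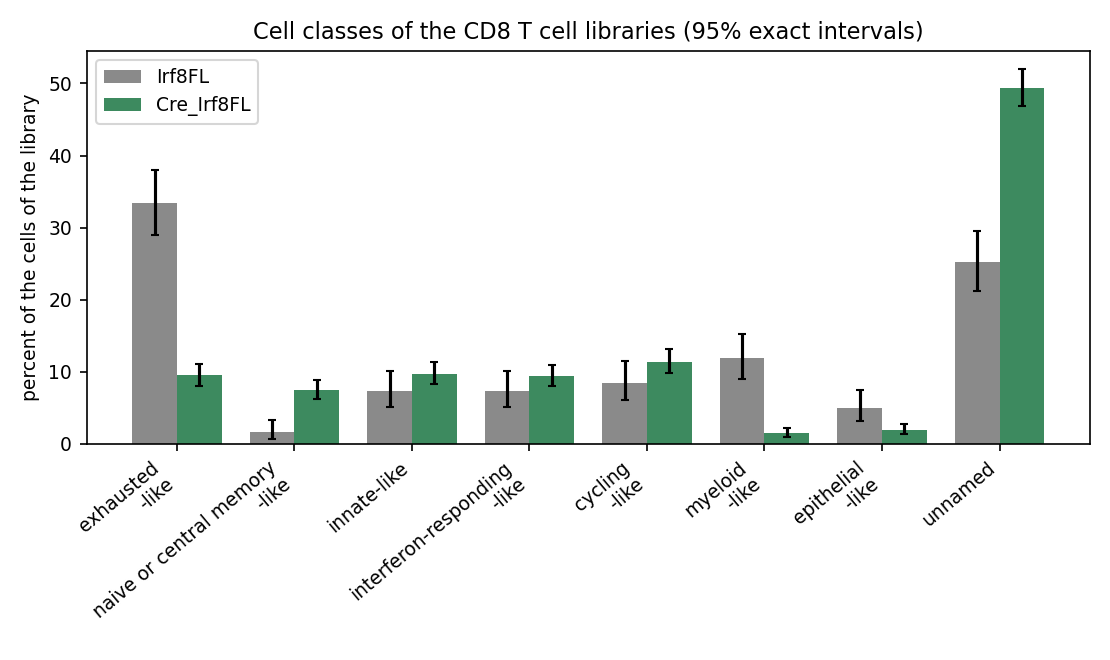
Percent of kept cells in each named class, clustered with all genes, in the Irf8FL library (grey, 440 cells) and the Cre_Irf8FL library (green, 1530 cells); lines are 95% exact binomial intervals. Exhausted-like cells were 33.4% and 9.48%, naive or central memory-like cells 1.59% and 7.39%.

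The inhibitory receptor gene Pdcd1 (ID 18566, chromosome 1, 94038305 to 94052553) stood at 150 CPM of summed UMIs in Cre_Irf8FL and 289 CPM in Irf8FL, a ratio of 0.518 (95% interval 0.480 to 0.558). Ratios below 1 were also found for the exhaustion genes Havcr2 (0.418), Lag3 (0.544), Tox (0.582), Entpd1 (0.610), Tigit (0.672) and Cd38 (0.840), and for Gzma (0.602), Ifng (0.664) and Gzmk (0.911). The interval of Ctla4 (0.987) and that of Cd69 (0.983) spanned 1. Genes of naive and memory T cells had ratios above 1, Ccr7 (8.18), Il7r (4.00), Tcf7 (2.32) and Slamf6 (1.68). So had Klrg1 (2.47), Mki67 (1.68), Prf1 (1.38), Itgae (1.19) and Gzmb (1.10). Irf8 stood at 0.828 and Cx3cr1 at 0.459. Among cells with CD3 and CD8 UMIs and without Cd4, Cx3cr1 turned to 2.80, Gzmb to 0.891 and Itgae to 0.971. There the interval of Havcr2 spanned 1 (0.713, 0.424 to 1.24), and those of Ctla4 (0.852, 0.734 to 0.992) and Cd69 (0.808, 0.758 to 0.862) lay below 1. Thinned to 2200 UMIs per cell, which left out 49 Irf8FL and 143 Cre_Irf8FL cells, 34.8% and 17.7% of cells had a Pdcd1 UMI (43.2% and 27.3% before thinning), against 0 of 38 epithelial-like cells. The epithelial-like cells had a median of 11380 UMIs and other cells 6271.

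Across fixed lists, the exhausted list had a median log2 ratio of −0.58, Cre_Irf8FL over Irf8FL, below all of 10000 random lists matched on expression (their range of 95% was −0.10 to 0.16), with 15 of 18 intervals below 1 and 2 above. The naive or central memory list had a median of 1.48 (10 of 11 intervals above 1). The cycling list had 0.37, the progenitor list 0.32, the cytotoxic list 0.19 and the heat shock list −0.89 (10 of 11 below 1). In cells with CD3 and CD8 UMIs and without Cd4 these medians were −0.51, 1.16, 0.10, 0.04, 0.31 and −0.81 in that order. Within exhausted-like cells Pdcd1 differed by less than its interval (ratio 0.918, 0.827 to 1.02) and so did Tox (1.08). Lower in Cre_Irf8FL were Gzma (0.0794), Ifng (0.301), Itgae (0.544), Lag3 (0.718), Tigit (0.813, 0.699 to 0.945), Gzmb (0.856) and Gzmk (0.864). Ccr7 was higher, with 9 against 0 UMIs. The class pools clusters 6 and 7, with 69 and 78 cells in Irf8FL and 89 and 56 in Cre_Irf8FL. Gzma was lower in both (0.126 and 0.0221), Ifng only in cluster 7 (1.21 and 0.157), Lag3 only in cluster 6 (0.586 and 0.909), and Pdcd1 moved apart (log2 ratios −0.52 and 0.26). Apart from Ccr7, the largest ratios of all rested on few cells. Ptn, Sparc, Krt6a and Il17b had 197, 98, 71 and 67 UMIs in Cre_Irf8FL and 0 in Irf8FL, those of Il17b all in 1 cell. Ido1 (251 against 2 UMIs), Tagln (112 against 2) and Gsta4 (514 against 23) likewise came mostly from cells outside the selection by CD3, CD8 and Cd4. The lowest ratios were those of Cd209d, Cd209f, Cd209a and Cd209g with 116, 113, 73 and 64 UMIs in Irf8FL and 0 in Cre_Irf8FL. The others were Ccl8 (1467 against 2 UMIs), Retnla (1421 against 36), Folr2 (146 against 3) and the carbonic anhydrase Car6 (269 against 8, with 213 in 1 cell). These lowest ratios also came from cells outside the selection by CD3, CD8 and Cd4. Of their Irf8FL UMIs, only 7 of Ccl8 and 1 of Retnla lay inside it. Except for Car6, these genes stood at 107 (Cd209a) to 2140 (Ccl8) CPM in myeloid-like cells. Car6 stood at 0 CPM in myeloid-like and 284 CPM in epithelial-like cells.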

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

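The tests of swapped labels, of dendritic cells in the sort and of cells other than CD8 T cells were chosen after the results they measure were seen, and the other tests before.

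Signals outside the sorted CD8 T cells stood out because they exceeded what a count of 0 allows. Myeloid-like cells made up 11.8% of Irf8FL and 1.44% of Cre_Irf8FL cells, where a count of 0 would allow 0.682% and 0.196%. Epithelial-like cells made up 5.00% and 1.90%. When only cells with CD3 and CD8 UMIs and without Cd4 were clustered, the naming rule still named 33 of 343 and 144 of 1463 cells myeloid-like and 47 and 161 epithelial-like, so there it was not specific for these cells.

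Irf8 stood at 1236 CPM in the libraries labelled CD11cCre_Irf8FL_TAM and at 517 CPM in Irf8FL_TAM. It was higher in 2 of 2 libraries under the Cre label, without passing the edgeR test. A swap of labels was tested through the genes higher in TAM than in MTM. Their median log2 fold change was −0.499 in the libraries labelled Cre, where a swap was predicted to raise them. This prediction assumes that loss of Irf8 lowers these genes, and no other libraries tested that. The test therefore cannot decide whether labels were swapped. Type 1 dendritic cells in the sort would raise their own markers, but the DC1 marker list had a median of −0.8192. The call of that list as lower was lost with an estimated correlation, so its fall is uncertain. Scaling would have to bring the fold under a bound of 0.5, but the lowest Irf8 log2 fold change over the other scalings was 1.172. Swapped labels, transcripts of a recombined gene that lack an exon, and a change of Irf8 expression with genotype stay open, since counts per gene cannot tell them apart.

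Mammary epithelial transcripts were higher in TAM than in MTM, and the list summed to 5155, 5569 and 11160 CPM in the TAM libraries against 2506, 2149 and 2403 CPM in MTM. The differences in Krt8, Krt18 and Epcam were divided by their levels in the epithelial-like cells of the single-cell libraries. Those cells were counted in UMIs, by another protocol and from other samples, so all shares derived from them are rough. The macrophage RNA that epithelial RNA would displace was not subtracted, so shares run too high for genes that macrophages also express. Taken at face value, the markers would imply that epithelial RNA made up 16.6% of TAM counts above MTM (9.43% to 24.4% by marker). This RNA could carry at least 50% of the difference in 6 of 8 other called epithelial genes (75.0%), which goes with epithelial cells or their RNA as a source of that list. By the same reckoning it could carry as much in 374 of 1065 genes higher in TAM (35.1%), between the bounds set beforehand. Since displaced RNA was not subtracted, this share is likely too high and cannot decide the question. For the genes higher in TAM as a whole, this source and TAM expression cannot be told apart. Its share was 0% for Vcam1, Clec9a, Siglech and H2-M2 and 0.00607% for H2-Ab1, against 122% for Csn3 and 186% for Lalba. Another gene of the epithelial list, Trf, had 3.42%. Shares above the whole difference, as for Csn3 and Lalba, mean that levels did not carry over exactly between the kinds of library.

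Exhausted-like cells made up a larger share of the Irf8FL library. Cells of other types in the sort do not account for it, since among cells with CD3 and CD8 UMIs and without Cd4 the shares were 37.6% (32.5 to 43.0) in Irf8FL and 9.91% (8.43 to 11.6) in Cre_Irf8FL. A single expanded clone was tested through the leading segment of exhausted-like cells of Irf8FL, Trbv1 (59.4%), although a segment is not a clone. Without cells of that segment 24% (18.7 to 29.9) of Irf8FL and 9.60% (8.08 to 11.3) of Cre_Irf8FL T cells were exhausted-like, which argues against that clone as the whole source. With 1 library per genotype, a difference between mice, between sorts or between genotypes stays open.

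Each of the 3 comparisons of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. TAM against MTM gave 2713 changed genes, TAM against Monocyte 4839 and MTM against Monocyte 3168 with 1 split each as large, the real one, and the highest other split gave 0 with edgeR. Every other split mixes both populations within each group, which widens the spread there. Their 0 calls therefore say nothing about chance.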

How the results depend on the processing

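The settings with the mammary epithelial level as a covariate, the clusters without marker list genes, the clusters of only cells with CD3 and CD8 UMIs and without Cd4, the estimated correlation for the dendritic cell sets and the replicate block of the gene sets were tests chosen after the results were seen. Of 7340 values for named bulk genes under alternatives, 6518 kept their direction and side of the threshold, 775 kept their direction only, 33 passed newly and 14 reversed. Of 166 list values 69 kept their call and 97 lost it with the same direction, and of 205 counts, overlaps and set medians 150 stayed within their bounds. Of 115 single-cell gene values 76 stayed, 33 moved and 6 reversed, and of 82 class shares 57 stayed. Counts and overlaps stayed if within 1.5 times the main value, odds ratios and set medians if they kept their direction and side of the threshold, single-cell ratios and shares if inside the main interval, and single-cell list medians if they moved by under 0.5 of the 95% range of random lists. The cause was not tested where none is given.

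The genes higher in TAM than in MTM numbered 1672 with upper-quartile scaling, 1717 with only the libraries of the 2 groups, 308 with all 13 libraries, 322 with the epithelial covariate and 472 to 794 over libraries left out. The genes lower in TAM than in MTM numbered 919 at an absolute log2 fold change of at least 1, 729 with all 13 libraries, 630 with the covariate and 898 to 1339 over libraries left out. At that fold, genes lower in TAM than in Monocyte numbered 1598 and genes lower in MTM than in Monocyte 900, by construction fewer; the latter were 779 with all 13 libraries and 917 to 1570 over libraries left out.

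For DC1 against DC2, the genes higher in DC1 than in DC2 and the genes lower in DC1 than in DC2 numbered 1066 and 1958 with DESeq2, 0 and 0 with edgeR on only the libraries of the 2 groups (2089 at an unadjusted p below 0.05; DESeq2 403 and 905), and 98 and 170 with the covariate. Over libraries left out they ran from 215 to 1639 and from 214 to 1454, and were lowest without DC1 replicate 2. For TAM against DC1, the genes higher in TAM than in DC1 ran from 841 to 1296 and the genes lower in TAM than in DC1 from 668 to 1160. The genotype fit of 4 libraries leaves 2 degrees of freedom for the spread, and the covariate takes up part of them. Between the genotype labels, the genes higher in CD11cCre_Irf8FL_TAM than in Irf8FL_TAM and the genes lower in CD11cCre_Irf8FL_TAM than in Irf8FL_TAM numbered 334 and 323 with DESeq2, 162 and 143 with no count filter, 86 and 75 with CPM of at least 5 and, unreliable for that reason, 340 and 224 with the covariate. Over libraries left out they ran from 0 to 473 and from 0 to 1041, with 0 by edgeR without either Irf8FL_TAM library (664 and 849 at an unadjusted p below 0.05).

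With the replicate block the genotype counts were 93 and 75, sharing 64 genes with the unblocked 64. The block too takes up part of the 2 degrees of freedom that the genotype fit leaves for the spread, so this rise is unreliable. The blocked counts for TAM against MTM were 942 and 1451, for TAM against Monocyte 2293 and 2324, for MTM against Monocyte 1691 and 1309, for DC1 against DC2 499 and 780 and for TAM against DC1 1250 and 1129. Replicate numbers were not taken as pairs, since correlations between libraries of the same number after removing group means ran from −0.317 to 0.408. All 3 were positive for MTM against Monocyte (0.408, 0.254 and 0.0543), so pairing there stays open. With the replicate block Xcr1 in MTM vs Monocyte turned to 0.34.

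The overlaps of TAM against MTM with DC1 against DC2, 0 and 0 as planned, were 91 and 192 with DESeq2 and 98 and 226 with calls of the 13-library fit. The median of the genes higher in DC1 than DC2 stayed at 0.275 with the estimated correlation, where its p rose to 0.15. The medians between genotype labels kept their direction in every setting run, from −0.774 to −0.353 for genes higher in TAM and from 0.488 to 1.38 for genes lower in TAM.

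The reversed bulk values were fold changes that had not passed the test. In MTM vs Monocyte, Xcr1 turned to 0.82 with the covariate, 0.33 without MTM replicate 2, 0.24 without MTM replicate 3 and 2.00 without Monocyte replicate 1 (−1.09 to 2.00 over libraries left out). Itgam turned to 0.11 without MTM replicate 2 (−0.21 to 0.11) and Irf8 to −0.037 without Monocyte replicate 1 (−0.037 to 0.45). In DC1 vs DC2, Vcam1 turned to 2.09 (−2.10 to 2.09 over libraries left out) and Ly6c2 to 0.63 (−0.80 to 0.63) without DC2 replicate 1, and Itgax to −0.42 without DC2 replicate 2 (−0.42 to 1.65). Ly6c2 between the genotype labels turned to −1.43 without CD11cCre_Irf8FL_TAM replicate 1 (−1.43 to 1.44 over libraries left out) and −2.49 with the covariate, and in TAM vs MTM the covariate turned Mrc1 to 0.0227 and Xcr1 to −0.56.

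In single cells, log2 ratios of Ido1 and Gsta4 turned to −0.17 and −1.18 as means of per-cell CPM, and in cells with CD3 and CD8 UMIs and without Cd4, Gsta4 turned to −0.0028, Gzmb to −0.17, Itgae to −0.0424 and Cx3cr1 to 1.48. The exhausted-like share of Cre_Irf8FL was 7.97% at resolution 0.4, and 3.20% against 19.1% in Irf8FL without marker list genes. The naive or central memory-like share of Cre_Irf8FL was 8.98% with no doublet removal, 4.18% without marker list genes and 6.08% in clusters of only cells with CD3 and CD8 UMIs and without Cd4; with the same number of cells per library the shares were 11.8% in Irf8FL and 50.2% in Cre_Irf8FL. Depth limits the shares of cells with a UMI, of which 42 of 46 moved from 2200 to 1100 UMIs per cell. The order of the libraries was the same for 23 of 24 genes between these depths, and for 22 between unthinned cells and 1100 UMIs.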

Other observations

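The test without cells holding dendritic cell markers and the genotype values of the dendritic cell gene sets were chosen after the results were seen; the C1q test was chosen before. Redrawing of cells was added after.

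Myeloid-like cells were found among the sorted T cells, 52 in Irf8FL and 22 in the Cre_Irf8FL library. They were named from general myeloid markers, and 46 and 15 of them had a UMI of a C1q gene. Retnla had 1420 and 36 UMIs in them and Folr2 145 and 1. The ratios below can therefore reflect a different mix of myeloid cells, which was not tested. Vcam1 stood at 337 CPM in those of Irf8FL and at 68.8 CPM in those of Cre_Irf8FL (ratio 0.204, 95% interval 0.109 to 0.353), where 1 cell held 12 of the 14 UMIs of Cre_Irf8FL. With cells redrawn the interval was 0 to 0.692. Ratios below 1 were also found for the mannose receptor Mrc1 (0.0493; redrawn 0 to 0.182) and the lipid carrier Apoe (0.395; 0.140 to 0.736), while the redrawn interval of H2-Ab1 (1.15) spanned 1. The chemokine Ccl8 had 1458 UMIs in 13 cells of Irf8FL, 497 of them in 1 cell, against 0. Irf8 stood at 796 CPM in the myeloid-like cells of Cre_Irf8FL against 255 CPM (ratio 3.12, 2.45 to 3.98), but 1 cell held 82 of the 162 UMIs, and 11 of 22 against 28 of 52 cells had an Irf8 UMI. Intervals without redrawing cover counting error only, and with cells redrawn the interval of this ratio was 0.893 to 6.15.

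In exhausted-like cells of Cre_Irf8FL, Trbv12-1 was the leading beta segment, at 41.3%. Among cells with CD3 and CD8 UMIs and without Cd4, the largest ratios of Cre_Irf8FL over Irf8FL included those of the costimulatory ligand Cd40lg (5.68, 3.39 to 10.3) and Ly6c2 (3.24, 3.02 to 3.48), and the lowest included myeloid and epithelial genes such as C1qa, C1qb, Csn3 and Lcn2. Free RNA, doublets and other cells passing the selection were not told apart as their source. Outside exhausted-like cells, T cells had ratios of 0.603 for Pdcd1, 0.532 for Tox, 1.67 for Tcf7 and 4.73 for Ccr7. In the libraries labelled CD11cCre_Irf8FL_TAM, the 200 genes most strongly higher in DC1 had a median log2 fold change of −0.15 (camera adjusted p = 0.000123, and adjusted p = 0.361 with an estimated correlation) and those lower in DC1 0.34 (adjusted p = 1.27e-14, and adjusted p = 0.029 with an estimated correlation).

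A hypothesis was that the higher Irf8 in myeloid-like cells of Cre_Irf8FL may come from dendritic cells. Among cells with a C1q UMI the ratio was 4.11 (3.22 to 5.27; 15 against 46 cells), but this criterion was too weak, since 1 such cell held 9 Xcr1, 19 Clec9a and 10 Flt3 UMIs. Without cells holding a UMI of Xcr1, Clec9a or Flt3 it was 2.61 (1.91 to 3.55; 14 against 44 cells), with dendritic cells whose markers went undetected left in. With cells redrawn these intervals were 1.21 to 7.68 and 0.971 to 4.74, so dendritic cells as a source of the difference can be neither shown nor excluded here.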
